A study of Homo sapiens with 9 samples.

How the data were processed

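Polyadenylated RNA was sequenced from MOLM13, a human acute myeloid leukemia cell line that carries a KMT2A fusion. Per the labels' protocols, virus carrying a control short hairpin RNA (shRNA) or 1 of 2 shRNAs against YTHDC1 was spun onto the cells for 1 h at 32 °C with polybrene at 10 ug/ml. The cells were incubated for 48 h and selected for 48 h with puromycin at 3 ug/ml. RNA was extracted from the harvested cells, and 1 ug per sample entered a stranded library kit that selects messenger RNA. The labels give 3 groups of 3 libraries each and number the libraries of a group, but do not say that they came from separate cultures. The p-values therefore measure only the spread between these libraries, which may be technical.

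The values are raw counts per transcript, deposited by the authors as whole numbers in 1 table with a column for each library. Per the submitters' processing notes, the reads were processed with STAR and DESeq on the human build hg19; the roles, versions and settings of these tools, the counting program, its use of strand and its treatment of reads with several places are not given in the sources used here. The table held 48102 transcript rows and 25679 gene symbols, and 9509 symbols had more than 1 row. Rows of the same gene repeated most of their reads: of 7288 such genes with at least 100 counts, 80.7% had a second row within 5% of the highest. The row with the highest total was therefore kept for each gene, and rows were never summed. A spreadsheet had turned 80 symbols into dates; 78 were restored through their transcript identifiers and 2 were left out. A RefSeq gene table of assembly GRCh38 matched 97.7% of the rows and was used only for names, chromosomes and gene types. The order of genes, the lengths that they span and their exon counts came from the GENCODE annotation of GRCh38. Both sources served only for such features, because the counts were made on another build. No coordinates are given for that reason. The per-sample columns not used numbered 0.

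Totals over the kept rows ran from 26455628 to 67558535 counts per library. A gene with 0 counts could hold up to 0.0444 to 0.113 CPM (counts scaled to the library total, in the usual unit), the value of 3 counts in the deepest and the shallowest library. Such floors and the intervals of ratios cover counting error only, since the reads carried no molecular identifiers. Levels are given as CPM after scaling by the trimmed mean of M values (TMM).

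Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, which left 16746; library sizes were scaled by TMM, and dispersions and the quasi-likelihood model were fitted with their robust options. All 9 libraries entered 1 fit with a mean per group, so that the groups share the estimate of spread. The contrasts were each YTHDC1 shRNA against control, the mean of both against control, and shRNA 2 against shRNA 1. Quasi-likelihood F-tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors (SE) of log2 fold changes come from the same fit. Counts of genes changed the same way were compared with the overlap of independent lists and with 20 simulations of unchanged groups against the same controls. The same steps were tested on simulated counts in which 200 genes were changed, with 15881 genes tested. Of the genes changed 4-fold, 94.0%, 95.5% and 97.0% were recovered with shRNA 1, shRNA 2 and the mean of both; of those changed 2-fold, 55.2%, 41.8% and 68.7% were, and of those changed 1.5-fold, 15.2%, 4.5% and 15.2%. False calls made up 5.2%, 4.0% and 6.9% of the calls.

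Gene lists were tested with camera in limma 3.58.1 at its preset correlation between genes of 0.01, on log2 CPM with a prior count of 2, and adjusted over the lists of a contrast. Camera with an estimated correlation and fry were run beside it. The 29 lists were m6A writers, erasers and readers; nucleolar ribosome biogenesis; other MYC targets; DNA replication; mitosis; monocyte and macrophage markers; granulocyte granule genes; the leukemic stem and KMT2A-fusion program; p53 targets; apoptosis regulators; interferon-stimulated genes; the ATF4 amino acid and stress response, endoplasmic reticulum chaperones, splicing factors, RNA export with polyadenylation and nuclear decay, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, mitochondrially encoded mRNAs, immediate early genes, the inflammatory and NF-kB response, replication-dependent histones, erythroid and megakaryocyte markers, lymphocyte markers, epithelial and stromal markers, small nucleolar RNA host and nuclear noncoding RNAs, antigen presentation and lysosome. The m6A list did not include YTHDC1, and the list of MYC targets did not include MYC.

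The genes named are set by a rule. YTHDC1, MYC and MCM2 to MCM7 are always named. From the averaged comparison, the rule takes the 12 rises and 12 falls with the largest smaller change of both shRNAs, among genes past 0.05 there with 1 direction with both shRNAs and a mean log2 CPM of at least 1. From shRNA 2 against shRNA 1 it takes the 10 highest and 10 lowest genes past 0.05 at that level. From each list it takes up to 3 members at each end of those past 0.05 in the averaged comparison, or all of them where at most 6 passed. XIST and Y-linked genes are not named. The groups, contrasts, tests, lists, rule and most alternatives were chosen before the data were examined.

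The alternatives were DESeq2-style size factors in edgeR, library size alone, DESeq2 1.42.0, limma voom, no filter beyond 1 count, a filter of at least 10 CPM in 3 libraries, the compared groups alone, the replicate number as a block, and each library left out in turn. After the data were seen, 2 more were added. They removed the genes that YTHDC1 shRNA 2 replicate 1 had lost, and took the first transcript of each gene in place of the highest. A gene was counted as lost in a library where its CPM, after division by the library's median ratio to the lower of the other libraries of its group, lay under 0.5 of that lower value, which had to be at least 5 CPM. Shared sequence was measured as the share of 50-base words of a gene's longest GENCODE transcript on GRCh38 that also occur in another gene. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 served for these measures and the plots.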

Results

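The series asked which genes differ in expression upon YTHDC1 knockdown in MOLM13 cells. Messenger RNA was sequenced from 9 libraries: 3 with a control shRNA, 3 labelled YTHDC1 shRNA 1 and 3 labelled YTHDC1 shRNA 2. The totals of control replicates 1 to 3 were 67124013, 65588653 and 66839149 counts over genes. Those of shRNA 1 were 58140085, 67558535 and 48590108, and those of shRNA 2 were 26455628, 50974549 and 47243451. The ribosomal RNA precursor RNA45S5, which poly(A) selection should largely remove, held 3.04%, 5.25% and 5.57% of the counts in the controls. It held 9.68%, 13.06% and 4.78% with shRNA 1, and 1.12%, 5.8% and 4.54% with shRNA 2. RNA45S5 was among the genes counted as lost in shRNA 2 replicate 1. A loss of reads can therefore not be told apart from less ribosomal RNA in the 1.12% of that library. No pair of libraries of a group agreed within sampling noise (chi-square per gene from 20.08 to 290.82), so none was treated as a library deposited more than once. This does not show that they came from separate cultures.

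YTHDC1, a nuclear reader of m6A in RNA encoded on chromosome 4, stood at 134, 139 and 122 CPM in control replicates 1 to 3 (mean 132 ± 8.52, SD, n = 3). The libraries labelled YTHDC1 shRNA 1 held 117, 103 and 134 CPM (118 ± 15.5, SD, n = 3), 89.4% of the control mean. Their log2 fold change of -0.16 ± 1.36 (SE) did not pass (edgeR adjusted p = 0.938). This SE rests on the spread shared by all 9 libraries, which shRNA 2 replicate 1 widens with its 0 counts. Nor did the change pass without that library (edgeR adjusted p = 0.271) or with the compared groups alone (edgeR adjusted p = 0.348). YTHDC1 mRNA was thus not measurably lower in the libraries labelled shRNA 1. With shRNA 2, replicates 2 and 3 held 61.4 and 52.5 CPM, while replicate 1 held 0 counts. By counting error alone, 0 counts allow up to 0.113 CPM before TMM scaling. However, shRNA 2 replicate 1 lacked reads of many genes that the other shRNA 2 libraries held, as described below. A loss of YTHDC1 reads can therefore not be told apart from a lower level in that library, and its 0 is not a measured knockdown. The log2 fold change with shRNA 2 was -1.79 ± 1.41 over all libraries, not past the test (edgeR adjusted p = 0.326). Without replicate 1, the mean of the shRNA 2 libraries was 56.9 ± 6.3 CPM (SD, n = 2), 43.1% of control, and YTHDC1 fell by 1.23 on the log2 scale (edgeR adjusted p = 2.2e-05). The mean of both shRNAs against control gave -0.98 (edgeR adjusted p = 0.513), and -0.71 without that replicate (adjusted p = 0.000212). For shRNA 2 against shRNA 1 the values were -1.63 (edgeR adjusted p = 0.434) and -1.05 (adjusted p = 0.000264).

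MYC, a transcription factor that drives growth and division, fell in every library of both YTHDC1 shRNA groups. Its level was 514, 531 and 494 CPM in the controls, 212, 217 and 160 CPM with shRNA 1, and 125, 125 and 130 CPM with shRNA 2. The fall was 2.62-fold with shRNA 1 (log2 fold change -1.39 ± 0.12 (SE), edgeR adjusted p = 1.42e-05) and 4.06-fold with shRNA 2 (-2.02 ± 0.13, edgeR adjusted p = 2.86e-07). MYC was lower with shRNA 2 than with shRNA 1 (-0.63 ± 0.12, edgeR adjusted p = 0.00258).

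**Figure D1:**
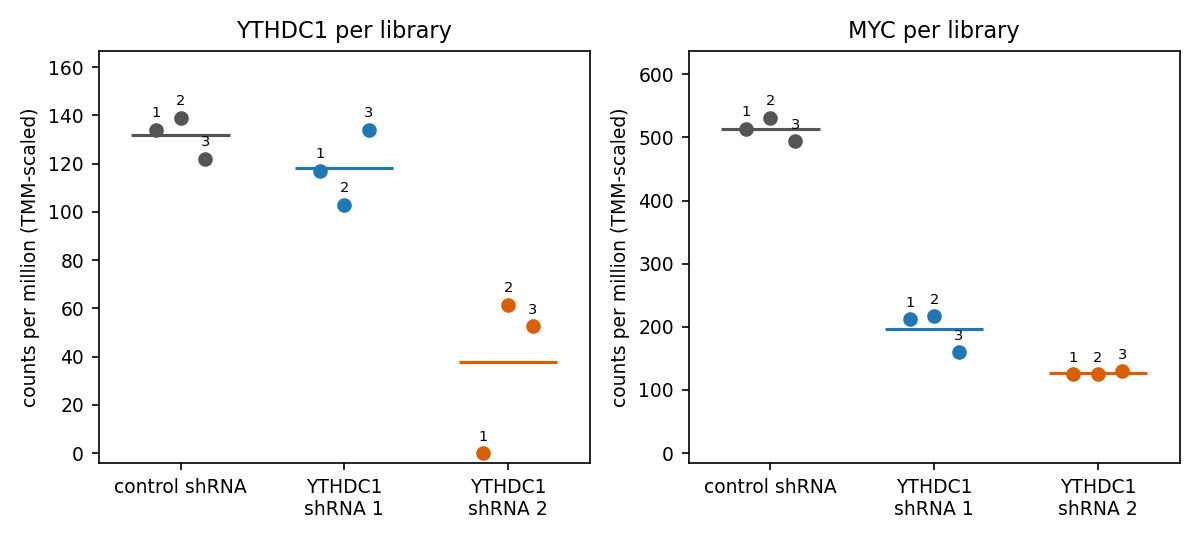
YTHDC1 (left) and MYC (right) in TMM-scaled CPM in each library, with the replicate number above each point and the mean of the 3 libraries as a line. YTHDC1 overlaps between control and shRNA 1 and has 0 counts in shRNA 2 replicate 1, while MYC lies at 494 CPM or more in the controls and at 217 CPM or less in the other libraries.

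YTHDC1 shRNA 2 replicate 1 stood apart from the other libraries of its group. Its log2 CPM correlated at 0.908 and 0.906 with them across genes, against 0.993 between the other 2, and it lay at 136 on the first principal component against 0.0841 and 0.457. In this library 502 of 10521 genes lay under 0.5 of the scaled CPM of both other shRNA 2 libraries, YTHDC1 and HLA-C among them. In the other 8 libraries this count ran from 0 to 75. Counts of changed genes without this library are given beside those of all 9.

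**Figure D2:**
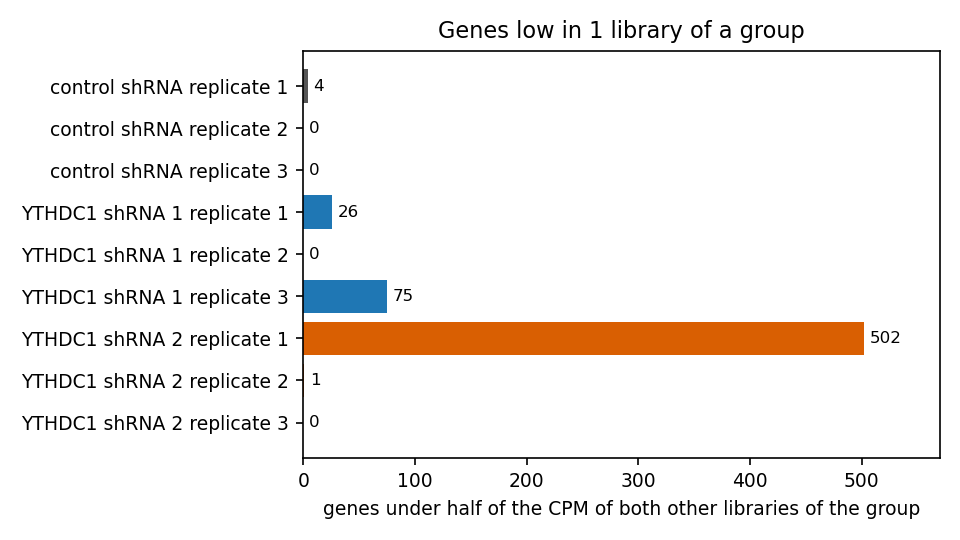
Number of genes in each library whose scaled CPM was under 0.5 of that in both other libraries of its group, among genes with at least 5 CPM in those. YTHDC1 shRNA 2 replicate 1 has 502 such genes, and the next library, YTHDC1 shRNA 1 replicate 3, has 75.

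In the libraries labelled YTHDC1 shRNA 1, where YTHDC1 itself was not measurably lower, CBS and SLC7A5 were lower and MDM2 and IFIT2 were higher than in control. CBS, an enzyme of transsulfuration, fell from 63 ± 4.22 to 6.31 ± 1.16 CPM (SD, n = 3), or 9.99-fold (log2 fold change -3.32 ± 0.17 (SE), edgeR adjusted p = 7.35e-07). SLC7A5, a transporter of large neutral amino acids, fell 6.06-fold (-2.60 ± 0.21, edgeR adjusted p = 1.36e-05). MDM2, the p53 target that encodes a ubiquitin ligase of p53, rose from 477 ± 22.5 to 1891 ± 248 CPM (1.99 ± 0.12, edgeR adjusted p = 1.78e-06). IFIT2, an interferon-induced gene, rose 7.26-fold (2.86 ± 0.17, edgeR adjusted p = 1.74e-06). Each of these 4 lay beyond every control library in 3 of 3 shRNA 1 libraries.

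Over all genes, 3419 rose and 3174 fell with shRNA 1, of which 1323 and 1038 changed more than 2-fold. Without shRNA 2 replicate 1, 3355 rose and 3551 fell, and 6290 of the calls (95.4%) remained in the same direction. By camera 10 lists were higher and 8 lower, and 0 of these calls held with an estimated correlation (lowest adjusted p = 0.143; 5 lists at an unadjusted p under 0.05), while fry called 10 higher and 10 lower. All 24 mitosis genes fell (median log2 fold change -1.45, camera adjusted p = 3.02e-14; adjusted p = 0.267 with an estimated correlation). Of the p53 targets 14 of 22 rose and 1 fell (camera adjusted p = 2.57e-06; adjusted p = 0.143 with an estimated correlation), and of the interferon-stimulated genes 12 of 24 rose and 3 fell (camera adjusted p = 0.0026; adjusted p = 0.143 with an estimated correlation). Endoplasmic reticulum chaperones were a higher list, with 10 of 17 members up and 2 down (median log2 fold change 0.46, camera adjusted p = 0.0227; adjusted p = 0.558 with an estimated correlation). HSPA5, the main chaperone of that compartment, rose 2.39-fold (1.26 ± 0.18, edgeR adjusted p = 0.000315). This list call was lost without control replicate 3 (camera adjusted p = 0.0613) or shRNA 1 replicate 1 (0.0542). Granulocyte granule genes were also higher, with 6 of 12 up and 1 down (camera adjusted p = 0.0241; adjusted p = 0.393 with an estimated correlation), which was lost without shRNA 1 replicate 2 (0.103). Epithelial and stromal markers had 4 of 8 up (camera adjusted p = 0.0423; adjusted p = 0.274 with an estimated correlation). That call was lost without control replicate 1 (0.0825), shRNA 1 replicate 2 (0.114) or shRNA 1 replicate 3 (0.0597). MPO, the myeloperoxidase of neutrophil granules, rose from 98.6 ± 32 to 290 ± 57.7 CPM (1.56 ± 0.28, edgeR adjusted p = 0.00272).

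With YTHDC1 shRNA 2, MKI67, CDK1, CTSG and BCL2 were lower and CTSB and CCL3 were higher than in control. MKI67, a marker of proliferating cells, fell from 393 ± 42.4 to 21.4 ± 3.19 CPM (SD, n = 3), or 18.4-fold (log2 fold change -4.20 ± 0.16 (SE), edgeR adjusted p = 2.1e-08). CDK1, the kinase that starts mitosis, fell 20.8-fold (-4.38 ± 0.22, edgeR adjusted p = 8.62e-08). CTSB, the lysosomal protease cathepsin B, rose from 96.1 ± 2.66 to 971 ± 216 CPM (3.34 ± 0.18, edgeR adjusted p = 1.08e-07). CCL3, a chemokine of macrophages, rose 66.3-fold (6.05 ± 0.21, edgeR adjusted p = 1.39e-08). CTSG, the granule protease cathepsin G, fell 8.82-fold from 873 ± 68.5 CPM (-3.14 ± 0.16, edgeR adjusted p = 7.63e-08), and BCL2, which blocks apoptosis, fell 5.82-fold (-2.54 ± 0.16, edgeR adjusted p = 2.87e-07). All 6 lay beyond every control library in 3 of 3 shRNA 2 libraries.

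Over all genes, 4600 rose and 4589 fell with shRNA 2, of which 2475 and 1829 changed more than 2-fold. Without replicate 1 the counts were 4408 and 4621, and 8329 of the 9189 calls (90.6%) remained in the same direction. By camera 7 lists were higher and 12 lower, and 0 of these calls held with an estimated correlation (lowest adjusted p = 0.109; 5 lists at an unadjusted p under 0.05), while fry called 8 higher and 13 lower. All 24 mitosis genes fell (median -3.59, camera adjusted p = 5.35e-17; adjusted p = 0.236 with an estimated correlation). All 26 monocyte and macrophage markers rose (median 2.93, camera adjusted p = 3.03e-12; adjusted p = 0.109 with an estimated correlation), as did 22 of 24 lysosome genes (median 1.29, camera adjusted p = 9.3e-09; adjusted p = 0.283 with an estimated correlation). Cholesterol synthesis was a lower list, with 15 of 20 members down and 1 up (median -0.73, camera adjusted p = 0.000435; adjusted p = 0.29 with an estimated correlation). FDPS, which makes farnesyl diphosphate, fell 3.07-fold (-1.62 ± 0.13, edgeR adjusted p = 1.98e-06). Splicing factors had 13 of 25 down and 1 up (camera adjusted p = 0.0038; adjusted p = 0.29 with an estimated correlation). SRSF2, a serine- and arginine-rich splicing factor, fell by 1.15 on the log2 scale (SE 0.12, edgeR adjusted p = 1.53e-05).

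Of the 12 largest rises shared by both shRNAs, 5 were protocadherin beta genes or pseudogenes on chromosome 5, a cluster of cell adhesion genes. As YTHDC1 was not measurably lower with shRNA 1, a shared direction is one between the labels, not between measured levels of knockdown. PCDHB15 rose from 0.207 ± 0.00274 CPM in control to 10.1 ± 3.97 with shRNA 1 and 22.7 ± 1.33 with shRNA 2 (SD, n = 3; averaged log2 fold change 6.17 ± 0.29 (SE), edgeR adjusted p = 6.65e-08). PCDHB12 had 1 count in the 3 controls together, and its ratio to control was 1065 with shRNA 1 (95% counting interval 191 to 42113) and 3390 with shRNA 2 (608 to 133935). PCDHB18, PCDHB19P and PCDHB11 rose by 7.78, 7.03 and 6.39 on the log2 scale. These genes share sequence, and how reads with several places were counted is not known, so the level of each is uncertain.

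Among the other 7 shared rises, TMEM119, a marker of microglia, rose 116-fold on average (6.86 ± 0.32, edgeR adjusted p = 5.94e-08). ADAMDEC1, a protease of the ADAM family, rose 85-fold on average (6.41 ± 0.18, edgeR adjusted p = 1.23e-08). CXCL8, which attracts neutrophils, rose from 6.63 ± 4.59 CPM to 194 ± 80.4 with shRNA 1 and 289 ± 17.1 with shRNA 2 (5.16 ± 0.59, edgeR adjusted p = 0.000349). OLR1, a receptor of oxidized low-density lipoprotein, and FCAR, the Fc receptor of IgA, rose by 6.63 and 6.03. FAM71F2 and GPR141 rose by 5.66 and 4.45. All 12 lay above every control in 6 of 6 libraries.

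Among the 12 largest shared falls, PHGDH, which starts serine synthesis, fell from 134 ± 9.82 CPM to 17.1 ± 3.33 with shRNA 1 and 15.2 ± 3.76 with shRNA 2 (-3.05 ± 0.16, edgeR adjusted p = 1.69e-07). CBS fell by the same average (-3.05 ± 0.13, edgeR adjusted p = 4.44e-08). TERT, the reverse transcriptase of telomerase, fell from 11.3 ± 3.84 to 1.63 ± 0.342 and 0.309 ± 0.123 CPM (-4.00 ± 0.26, edgeR adjusted p = 5.41e-07). TONSL, of replication fork repair, and CHTF18, of a clamp loader, had averages of -2.95 and -2.71. The histone genes HIST1H4I and HIST1H2AE had averages of -3.40 and -2.66, and UBL4B, FJX1 and C21orf58 of -3.71, -2.92 and -3.05. HIST2H3A and HIST2H3C, which had identical values, averaged -3.96 ± 1.09 (edgeR adjusted p = 0.0227) but did not pass with shRNA 1 alone (adjusted p = 0.173). Their averaged call was lost when any 1 of 6 libraries was left out, with log2 fold changes from -4.12 to -3.75 and adjusted p from 0.0513 to 0.0595. Those were each control, shRNA 1 replicates 1 and 3, and shRNA 2 replicate 3, while without shRNA 2 replicate 1, which had lost both genes, the value was -3.69 (adjusted p = 3.7e-05). All 12 lay below every control in 6 of 6 libraries.

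In the averaged comparison 4399 genes rose and 4391 fell, of which 1916 and 1337 changed more than 2-fold. Without shRNA 2 replicate 1, 4276 rose and 4691 fell, and 8266 of the calls (94.0%) remained in the same direction. Both shRNAs called 2620 genes higher and 2544 lower, and 154 in opposite directions. Independent lists of the same sizes would share 939 and 870, and simulated unchanged groups against the same controls shared 0.05 on average. Without shRNA 2 replicate 1, both called 2515 genes higher, 2802 lower and 116 in opposite directions. Log2 fold changes of both shRNAs correlated across genes, which are not independent replicates, at Pearson's r = 0.81 and Spearman's rho = 0.77, against r = 0.48 in the simulations. Their covariance was 0.87 against 0.08 simulated, a difference of 0.79, and 79.4% of the genes had the same sign against 66.3%. The 3 controls cannot be divided into parts of at least 2 libraries, so part of the excess over independent lists may come from the shared controls, which the simulations include.

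**Figure D3:**
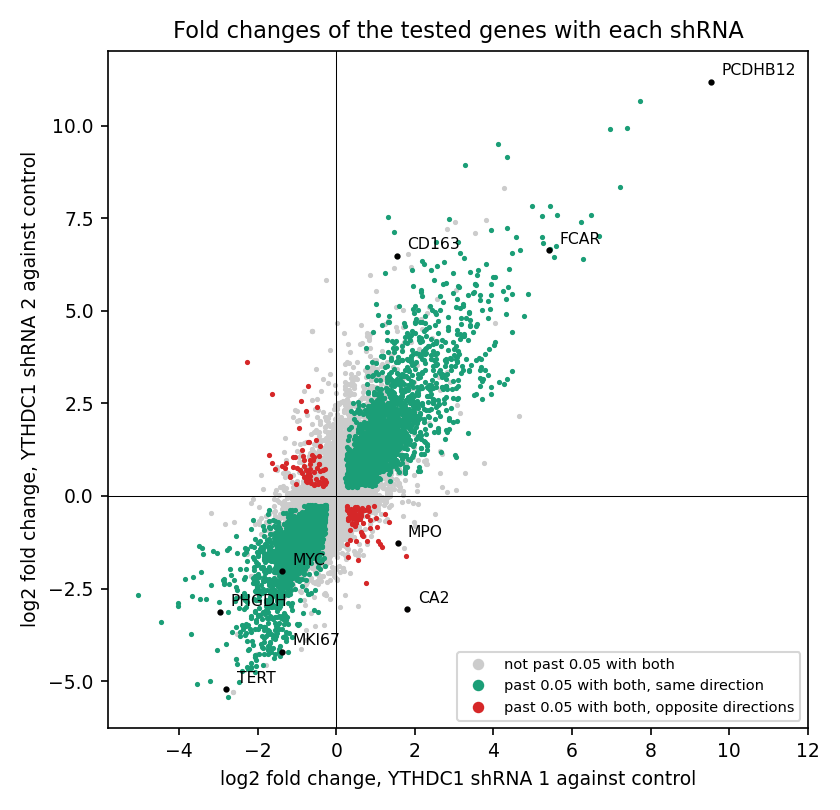
Log2 fold change against control of each tested gene, without XIST and Y-linked genes, with YTHDC1 shRNA 1 (x axis) and YTHDC1 shRNA 2 (y axis). Green points passed the adjusted threshold with both in 1 direction (5155 genes), red points in opposite directions (154), and grey points did not pass with both; black points are genes named in the text, among them CA2 and MPO, which rose with shRNA 1 and fell with shRNA 2.

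Lists of growth and division were lower in the averaged comparison, which includes the shRNA 1 libraries where YTHDC1 was not measurably lower. For every list call here, the test was camera, and the p with an estimated correlation is given beside it. All 24 mitosis genes fell (median log2 fold change -2.51, camera adjusted p = 1.63e-16; adjusted p = 0.213 with an estimated correlation), the count being 24 adjusted over the list alone. AURKB, a mitotic kinase, and BIRC5, its partner in the chromosomal passenger complex, fell by 3.34 and 3.22. All 32 DNA replication genes fell, also adjusted over the list alone (median -1.93, camera adjusted p = 2.27e-17; adjusted p = 0.175 with an estimated correlation). CDC45 and MCM10, which help to start replication, fell by 3.44 and 3.32. The replicative helicase genes MCM2, MCM3, MCM4, MCM5, MCM6 and MCM7 fell by 2.76, 1.81, 2.01, 2.27, 1.80 and 2.44. MCM4, for example, went from 415 ± 27 CPM to 135 ± 12.6 with shRNA 1 and 78.4 ± 3.06 with shRNA 2 (SD, n = 3). Of 13 replication-dependent histones 12 fell, and 12 adjusted over the list alone (median -2.08, camera adjusted p = 9.42e-07; adjusted p = 0.297 with an estimated correlation).

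Nucleolar ribosome biogenesis had 26 of 27 members down, and 27 adjusted over the list alone (median -0.88, camera adjusted p = 4.42e-10; adjusted p = 0.232 with an estimated correlation). BOP1 and GRWD1, which act in assembly of the large ribosomal subunit, fell by 1.64 and 1.61. Of the other MYC targets 21 of 25 fell and 1 rose, or 22 and 1 adjusted over the list alone (median -0.77, camera adjusted p = 1.41e-07; adjusted p = 0.263 with an estimated correlation). CDC25A, a phosphatase that activates cyclin-dependent kinases, and SLC7A5 fell by 2.69 and 2.43. Cytosolic ribosomal proteins had 11 of 34 down, or 9 adjusted over the list alone (median -0.31, camera adjusted p = 0.00284; adjusted p = 0.579 with an estimated correlation), and fry did not call them (adjusted p = 0.0632). The ATF4 amino acid and stress response had 16 of 18 down and 1 up, also adjusted over the list alone (median -1.97, camera adjusted p = 1.59e-07; adjusted p = 0.263 with an estimated correlation). CHAC1, which degrades glutathione, fell by 3.03 and ATF3, a stress-induced transcription factor, rose by 0.55.

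Monocyte and macrophage markers had 25 of 26 up, also adjusted over the list alone (median 2.30, camera adjusted p = 1.28e-12; adjusted p = 0.122 with an estimated correlation). CLEC7A, the beta-glucan receptor, and VCAN, a proteoglycan of monocytes, rose by 5.16 and 4.84. FCGR3A, an Fc receptor of IgG, had 3 counts in the 3 controls, and its ratio to control was 18.6 with shRNA 1 (95% counting interval 6 to 93.5) and 67.2 with shRNA 2 (22.5 to 330). Lysosome genes had 22 of 24 up, or 23 adjusted over the list alone (median 1.12, camera adjusted p = 8.61e-09; adjusted p = 0.297 with an estimated correlation). CTSB and GRN, which encodes progranulin, rose by 2.25 and 2.06. The inflammatory and NF-kB response had 15 of 17 up and 1 down, also adjusted over the list alone (median 0.93, camera adjusted p = 9.42e-07; adjusted p = 0.153 with an estimated correlation). CCL3 rose by 4.72 and CCL5, a chemokine that attracts T cells, fell by 0.46. CCL4 had 1 count in the controls, and its ratio was 24.4 with shRNA 1 (95% counting interval 3.93 to 1011) and 1050 with shRNA 2 (188 to 41532). Immediate early genes had 12 of 20 up and 2 down, also adjusted over the list alone (median 1.07, camera adjusted p = 0.00191; adjusted p = 0.32 with an estimated correlation). JUN, a subunit of AP-1, rose by 2.50 and IER2 fell by 0.71.

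**Figure D4:**
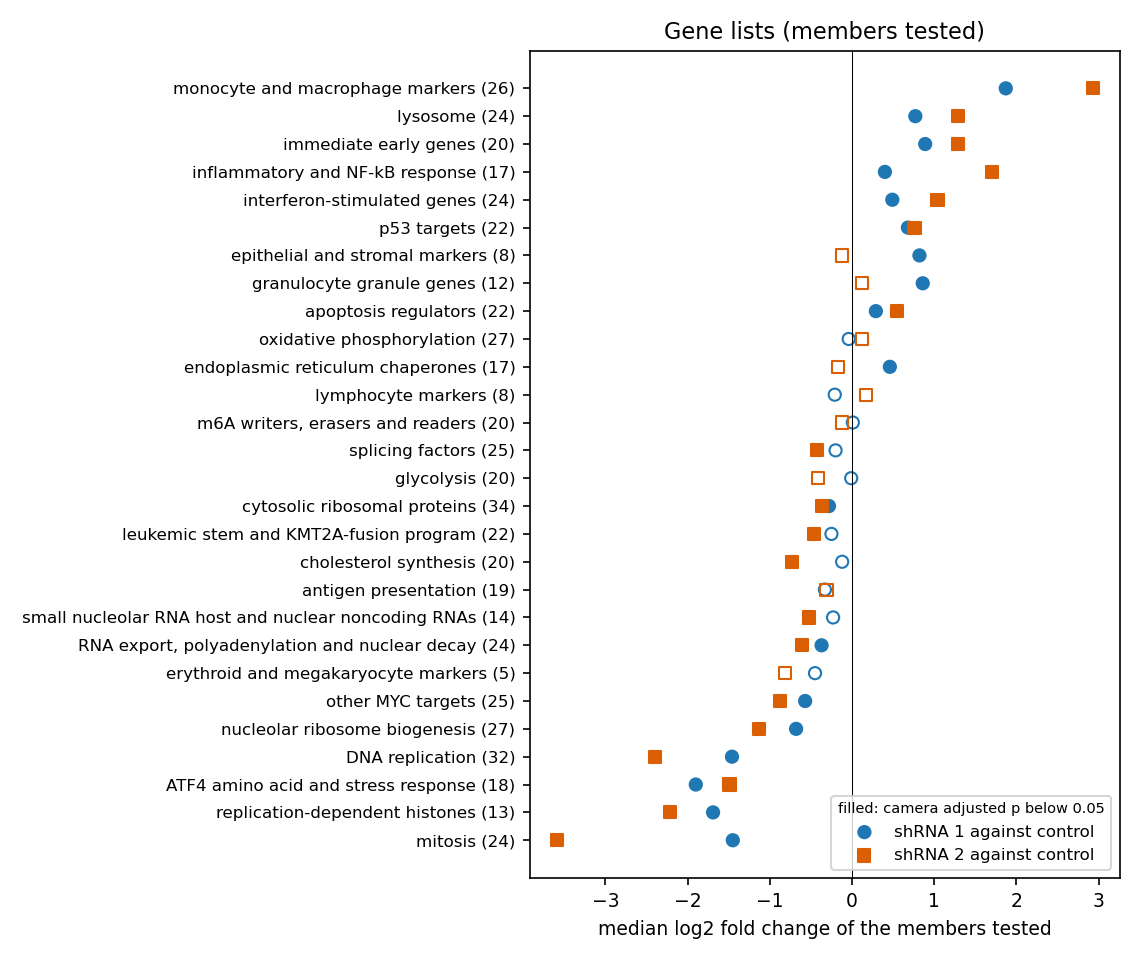
Median log2 fold change of the tested members of each gene list with YTHDC1 shRNA 1 (circles) and shRNA 2 (squares) against control, with the number tested in parentheses. Filled symbols have a camera adjusted p below 0.05 at the preset correlation, and none of them passes with an estimated correlation (lowest adjusted p 0.143 and 0.109); monocyte and macrophage markers lie highest and mitosis genes lowest with shRNA 2.

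The p53 targets had 14 of 22 up and 1 down, also adjusted over the list alone (median 0.76, camera adjusted p = 8.45e-05; adjusted p = 0.153 with an estimated correlation). BTG2, an antiproliferative gene, and CDKN1A, which encodes the cyclin-dependent kinase inhibitor p21, rose by 2.67 and 1.87, and SESN2 fell by 0.78. Apoptosis regulators had 12 of 22 up and 1 down, or 12 and 2 adjusted over the list alone (median 0.39, camera adjusted p = 0.00284; adjusted p = 0.122 with an estimated correlation). Those that rose the most, BIRC3, BCL2A1 and CFLAR (4.16, 3.36 and 1.62), are known to restrain cell death, as is BCL2, which fell by 1.88. Interferon-stimulated genes had 15 of 24 up and 3 down, also adjusted over the list alone (median 0.79, camera adjusted p = 0.000356; adjusted p = 0.122 with an estimated correlation). IFIT3 and IFIT2 rose by 2.39 and 2.34, and USP18, which limits interferon signalling, fell by 0.85.

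The leukemic stem and KMT2A-fusion program had 13 of 22 down and 4 up, also adjusted over the list alone (median -0.34, camera adjusted p = 0.0285; adjusted p = 0.32 with an estimated correlation). It was not called with library size alone (camera adjusted p = 0.0643). MEIS1, a homeobox gene of this program, fell by 1.15, and LMO2 rose by 1.15. The largest change of a called member was a rise, that of KIT, 4.5-fold on average. KIT rose 4.72-fold with shRNA 1 and 4.26-fold with shRNA 2. RNA export, polyadenylation and nuclear decay had 17 of 24 down and 0 up, or 17 and 1 adjusted over the list alone (median -0.52, camera adjusted p = 0.000152; adjusted p = 0.32 with an estimated correlation). NXT1, of the mRNA export receptor, fell by 1.05. Splicing factors had 11 of 25 down and 2 up, also adjusted over the list alone (median -0.20, camera adjusted p = 0.0137; adjusted p = 0.378 with an estimated correlation). Small nucleolar RNA host and nuclear noncoding RNAs had 9 of 14 down and 2 up, also adjusted over the list alone (median -0.37, camera adjusted p = 0.0222; adjusted p = 0.297 with an estimated correlation). The 2 that rose, MALAT1 and NEAT1 (1.58 and 1.39), are retained in the nucleus, while SNHG15 and SNHG8 fell by 0.95 and 0.86. Cholesterol synthesis had 11 of 20 down and 2 up, also adjusted over the list alone (median -0.35, camera adjusted p = 0.00849; adjusted p = 0.448 with an estimated correlation).

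The remaining lists were not called by camera in the averaged comparison. Fry called 8 lists higher and 13 lower there, and of the remaining ones it called epithelial and stromal markers higher (fry adjusted p = 0.000426) and erythroid and megakaryocyte markers (0.0249) and glycolysis (0.0249) lower. The m6A writers, erasers and readers had 3 up and 4 down of 20, also adjusted over the list alone (camera adjusted p = 0.639); YTHDF3, a cytoplasmic m6A reader, rose by 0.52, and METTL14, of the methyltransferase complex, fell by 0.44. Granulocyte granule genes had 5 up and 2 down of 12, also adjusted over the list alone (camera adjusted p = 0.303). CTSG fell by 1.80 and GFI1 fell 1.24-fold, while CEBPE rose 3.68-fold on average. FPR1 had 2 counts in the 3 controls. Its ratio to control was 10.5 with shRNA 1 (95% counting interval 2.51 to 93.1) and 60.2 with shRNA 2 (16.1 to 505). MMP9 had 3 counts there, and its ratios were 1.94 (0.377 to 12.5) and 69.6 (23.4 to 342). Endoplasmic reticulum chaperones had 6 up and 1 down of 17, also adjusted over the list alone (camera adjusted p = 0.433). Glycolysis had 5 up and 9 down of 20, or 5 and 10 adjusted over the list alone (camera adjusted p = 0.132), with HK1 rising by 1.74 and ALDOC falling by 1.63. Oxidative phosphorylation had 2 up and 4 down of 27, and 0 of either adjusted over the list alone (camera adjusted p = 0.832), with a median of 0.03 and a mean of -0.03. Antigen presentation had 1 up and 2 down of 19, or 1 and 0 adjusted over the list alone (camera adjusted p = 0.433). Without shRNA 2 replicate 1, which had lost many of these genes, 6 were up and 9 down (camera adjusted p = 0.324). Of markers of other cell types, erythroid and megakaryocyte genes had 3 down of 5 tested (camera adjusted p = 0.187), lymphocyte genes 3 up and 1 down of 8 (0.887, with a median of -0.05 and a mean of 0.42), and epithelial and stromal genes 3 up and 1 down of 8 (0.11), the same counts adjusted over the list alone. PECAM1, an adhesion molecule of endothelium that monocytes also express, rose by 2.75, and PAX5, a B cell factor, fell by 1.13. CD22 of the lymphocyte list and VWF of the epithelial and stromal list each rose 9.13-fold on average. Of 13 mitochondrially encoded mRNAs, 0 could be tested.

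**Figure D5:**
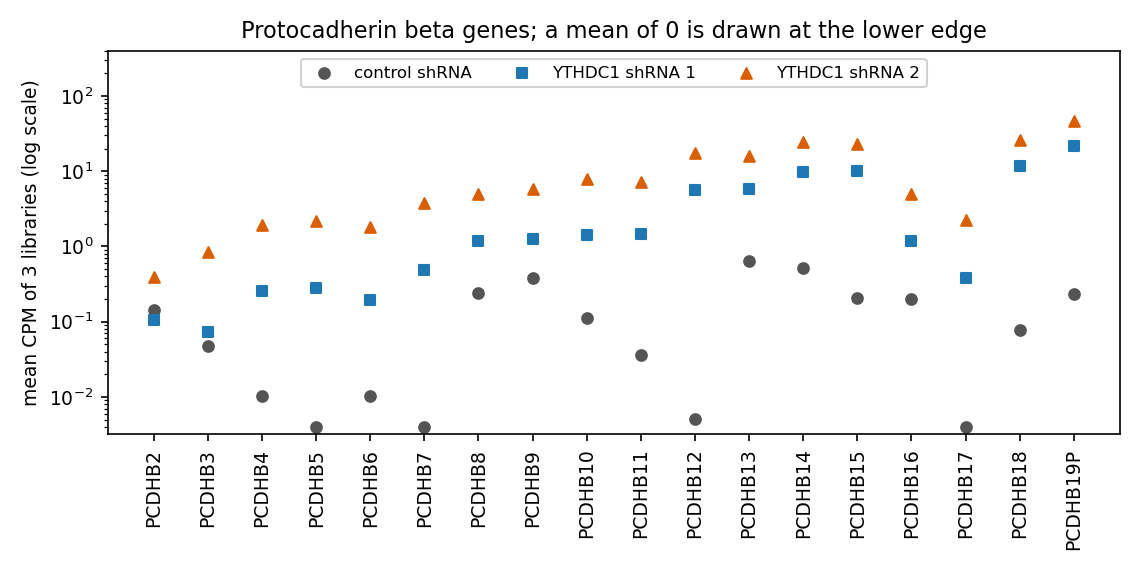
Mean CPM over the 3 libraries of each group (log scale) for the 18 tested protocadherin beta genes and pseudogenes, where a control mean of 0 is drawn at the lower edge. All lie higher with YTHDC1 shRNA 2 than in control, and all but PCDHB2, named after its values were seen, lie higher with YTHDC1 shRNA 1 than in control.

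Setting shRNA 2 against shRNA 1 asks whether the shRNAs differ from each other; YTHDC1 was not measurably lower in the libraries labelled shRNA 1. SPP1, CSF1 and ACP5 were higher, and CA2 and MPO lower, with shRNA 2. SPP1, which encodes osteopontin, stood at 64.6 ± 22.6 CPM with shRNA 2 and 1.27 ± 0.462 with shRNA 1 (SD, n = 3; log2 fold change 5.67 ± 0.32 (SE), edgeR adjusted p = 3.74e-06). CSF1, a growth factor of macrophages, was 68.6-fold higher (6.10 ± 0.37, edgeR adjusted p = 2.08e-06), and ACP5, tartrate-resistant acid phosphatase, was 74.5-fold higher (6.22 ± 0.39, edgeR adjusted p = 4.98e-06). CA2, a carbonic anhydrase, stood at 2.18 ± 0.456 CPM with shRNA 2 and 63.6 ± 12.1 with shRNA 1, between which lay the control at 18.1 ± 4.76 (-4.87 ± 0.26, edgeR adjusted p = 1.92e-06). MPO likewise stood at 40.9 ± 10.7 and 290 ± 57.7 CPM on either side of control (-2.83 ± 0.30, edgeR adjusted p = 0.000182).

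Over all genes 2597 were higher and 2767 lower with shRNA 2 than with shRNA 1, of which 1178 and 602 differed more than 2-fold. Without shRNA 2 replicate 1, 2182 were higher and 2253 lower, and 4121 of the calls (76.8%) remained in the same direction. The count of lower genes was 1842 without shRNA 2 replicate 3, and 1236 with library size alone. By camera 5 lists were higher and 10 lower, and 0 of these calls held with an estimated correlation (lowest adjusted p = 0.224; 3 lists at an unadjusted p under 0.05), while fry called 7 and 12. The count of higher lists was 3 without shRNA 1 replicate 3. Mitosis genes were lower in 24 of 24 (median -2.10, camera adjusted p = 4.74e-20; adjusted p = 0.414 with an estimated correlation), and the inflammatory and NF-kB response was higher in 14 of 17 (median 1.54, camera adjusted p = 2.38e-10; adjusted p = 0.224 with an estimated correlation). Monocyte and macrophage markers were higher in 18 and lower in 4 of 26 (median 1.07, camera adjusted p = 3.35e-05; adjusted p = 0.414 with an estimated correlation).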

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

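Among the tests below, the one without the library that lost genes, the one of opposite directions, the sizes of the changes shared by both shRNAs, the one with the lost genes removed and the one with the first transcript of each gene were chosen after the results were seen. The tested difference between the shRNAs, in libraries of which those labelled shRNA 1 did not hold measurably less YTHDC1 mRNA, singled out 2597 genes higher and 2767 lower with shRNA 2. Of the named genes, ACP5 (log2 fold change 6.22), CSF1 (6.10), SPP1 (5.67), KCP (5.66), CD163 (4.95), SLC26A11 (4.81), GPNMB (4.78), CLEC7A (4.61) and SDS (4.51) were higher with shRNA 2. CD163 is a scavenger receptor of macrophages and SDS a serine dehydratase. CA2 (-4.87), SORCS2 (-3.10), DLGAP5 (-2.96), DEPDC1 (-2.88), MPO (-2.83), MKI67 (-2.81), CDK1 (-2.81), MAD2L1 (-2.74) and BIRC5 (-2.71) were lower, and DLGAP5, MKI67, CDK1, MAD2L1 and BIRC5 act in dividing cells.

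The chemokine gene CCL4L2 (4.39, edgeR adjusted p = 0.0491) and HSD17B8 (-3.22, edgeR adjusted p = 0.0334) also differed, but shRNA 2 replicate 1 had hardly any of their reads. Without that library their log2 fold changes were 4.96 (adjusted p = 3.72e-05) and -2.70 (adjusted p = 4.74e-06). Without any 1 of the other 8 libraries CCL4L2 did not pass (3.85 to 5.43, adjusted p from 0.075 to 0.128). HSD17B8 did not pass without any 1 control, shRNA 1 replicate 1 or 2, or shRNA 2 replicate 2 or 3 (-3.79 to -3.01, adjusted p from 0.0616 to 0.0926). In other settings, CCL4L2 did not pass with library size alone (0.0501), limma voom (0.152), no filter (0.0778), the compared groups alone (0.134) or the first transcript of each gene (0.0555), and HSD17B8 not with no filter (0.0515) or the compared groups alone (0.127).

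List medians of shRNA 2 against shRNA 1 were lower for nucleolar ribosome biogenesis (-0.42), DNA replication (-0.80), mitosis (-2.10), endoplasmic reticulum chaperones (-0.73), splicing factors (-0.24), RNA export with polyadenylation and nuclear decay (-0.19) and cholesterol synthesis (-0.71). They were higher for monocyte and macrophage markers (1.07), the inflammatory and NF-kB response (1.54) and lysosome (0.56). None of these calls passed with an estimated correlation (lowest adjusted p = 0.224). With library size alone, splicing factors (camera adjusted p = 0.0577), the RNA export list (0.105), interferon-stimulated genes (0.0576) and the leukemic stem and KMT2A-fusion program (0.126) were not called. Fry did not call replication-dependent histones (adjusted p = 0.0882). Further calls each ended when 1 library was left out. These were granulocyte granule genes (-0.66; camera adjusted p = 0.0558 without shRNA 1 replicate 2 and 0.0565 without shRNA 2 replicate 2) and immediate early genes (0.34; 0.0565 without shRNA 1 replicate 3). The leukemic stem and KMT2A-fusion program (-0.28) was lost without shRNA 1 replicate 3 (0.0844), shRNA 2 replicate 1 (0.0932) or shRNA 2 replicate 2 (0.0524). Replication-dependent histones (-0.47) were lost without shRNA 1 replicate 1 (0.0947) or 2 (0.131), or shRNA 2 replicate 1 (0.0633) or 2 (0.107). Interferon-stimulated genes (0.40) were lost without any 1 library except shRNA 2 replicate 3 (0.0506 to 0.0951), and with the genes lost in shRNA 2 replicate 1 removed (0.0659).

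Among explanations for the difference between the shRNAs, the library that lost genes was argued against as the whole cause, because 4121 of the 5364 calls remained in the same direction without it. That the changes are the same but larger with shRNA 2 was not settled. Of 2775 genes that differed between the shRNAs and from control with shRNA 1, 64.9% differed in the direction of the shRNA 1 change. This lay between the bounds of 60% and 80% set beforehand. The shRNA 1 libraries enter both comparisons with opposite sign, so their noise can lower this share. Of 5155 genes called the same way with each shRNA, 73.7% changed more with shRNA 2, with a median ratio of log2 fold changes of 1.34 (XIST and Y-linked genes left out of both counts). The 154 genes called in opposite directions may reflect effects of 1 shRNA on other transcripts, or a response that turns with the level of YTHDC1, and these cannot be told apart without a rescue or a further shRNA. A biological difference from the lower YTHDC1 level with shRNA 2 stays open as a hypothesis.

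Other splits of the libraries into groups of the same sizes were tested as planned. The 10 splits of 6 libraries are too few for a share under 0.05. The real splits called 6593, 9189 and 5364 genes with shRNA 1, with shRNA 2 and between them, and the highest other split called 0 in each, so that 1 split gave as many. For lists the real values were 18, 19 and 15 and the highest others 17, 19 and 13, and 1, 3 and 1 splits gave as many. Among the 84 splits of 9 libraries, 1 gave at least the 8790 genes of the averaged comparison (highest other 4123) and 1 at least the 5164 genes called the same way (highest other 1922). Other splits mix libraries of different groups, which widens the spread within a group, and 4 and 1 of them gave any such gene. As the libraries may not be separate cultures, the splits cannot exclude a chance difference between cultures. For lists called in the averaged comparison, 7 of 84 splits gave at least the real 19 (highest other 20), so chance was not excluded. Splits that keep most libraries of a group together still hold part of the difference between groups, so this count cannot settle the question.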

How the results depend on the processing

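The alternatives that removed the genes lost in shRNA 2 replicate 1 or took the first transcript of each gene were chosen after seeing the data. Counts of changed genes stayed within 1.5 times of the reported ones except as follows. With the strict filter, 2994 and 3046 genes were higher and lower with shRNA 2 and 2914 higher on average, since fewer genes were tested. With library size alone 1236 were lower with shRNA 2 than with shRNA 1. That scaling moved the median of all genes by 0.17 with shRNA 2 and 0.18 between the shRNAs, and the share of higher calls from 50.1% to 62.2% and from 48.4% to 71.5%. Leaving out 1 library gave 1842 (without shRNA 2 replicate 3) to 3203 lower genes between the shRNAs; the cause was not tested. YTHDC1 ranged from -2.33 to -1.23 with shRNA 2, -1.25 to -0.71 on average and -2.17 to -1.05 between the shRNAs, and passed only without shRNA 2 replicate 1. With limma voom it was -4.51, -2.34 and -4.34 and did not pass. Of 164 calls of named genes, 26 were lost in at least 1 alternative and 0 reversed.

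With an estimated correlation, 0 lists were higher and 0 lower with shRNA 1, 0 and 0 with shRNA 2, 0 and 0 on average and 0 and 0 between the shRNAs. Lists higher between the shRNAs ranged from 3 (without shRNA 1 replicate 3) to 6. Directions of some lists turned, with causes not tested. The leave-one-out adjusted p ranges were 0.536 to 0.995 for m6A genes with shRNA 1 and, for oxidative phosphorylation, 0.0268 (without shRNA 1 replicate 1) to 0.812 with shRNA 1, 0.523 to 0.965 with shRNA 2, 0.393 to 0.893 on average and 0.008 (without shRNA 1 replicate 1) to 0.762 between the shRNAs. They were 0.842 to 0.998 for granulocyte granule genes with shRNA 2 and 0.724 to 0.936 for lymphocyte markers on average. Between the shRNAs they were 0.0217 (without shRNA 1 replicate 3) to 0.984 for cytosolic ribosomal proteins, 0.523 to 0.915 for erythroid and megakaryocyte markers and 0.143 to 0.665 for antigen presentation. Directions also turned for oxidative phosphorylation on average with library size alone (0.888), for lymphocyte markers with fry (0.663), and for antigen presentation without the lost genes (0.549 with shRNA 2, 0.87 on average, 0.215 between the shRNAs).

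The replicate numbers did not clearly pair the libraries. Deviations of same-numbered control and shRNA 1 libraries correlated at 0.57, 0.05 and 0.21, those with shRNA 2 from -0.09 to 0.04. Of 9 libraries, 3 lay nearest to their own number. The shRNA 2 deviations were taken from a group mean that includes shRNA 2 replicate 1. The genes lost in that library can hide a pairing, so the values with shRNA 2 cannot exclude one. With the replicate number as a block, 3392 and 3181 genes were higher and lower with shRNA 1, 4645 and 4516 with shRNA 2, 4413 and 4334 on average and 2602 and 2709 between the shRNAs. Of the values compared under the block, 289 stayed, 7 ended, 1 was gained (each as a call) and 1 turned, granulocyte granule genes with shRNA 2 (adjusted p = 0.96). The calls that ended were those of epithelial and stromal markers with shRNA 1 (0.0506), HIST2H3A and HIST2H3C (0.0569), GNLY (0.059) and HLA-C (0.0739) on average, and HSD17B8 (0.0764) and CCL4L2 (0.209) between the shRNAs. The ATF4 list was gained between the shRNAs (0.0288).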

Other observations

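The gene families and the gene spans below were chosen after the data were seen, as were the neighbours of the protocadherin genes, the test of reads from the most abundant protocadherin and all tests of the lost genes. Genes of some families of surface receptors were counted in the averaged comparison, which includes the shRNA 1 libraries where YTHDC1 was not measurably lower; no enrichment test was run. All 11 tested SIGLEC genes, which bind sialic acid, rose (median log2 fold change 2.34), and 9 did without shRNA 2 replicate 1. Of the leukocyte immunoglobulin-like receptors (LILR) 9 of 10 rose (1.6), of the C-type lectin genes (CLEC) 14 of 20 (2.75) and of the CD300 genes 5 of 5 (1.09). With shRNA 1 alone, 4 of 11, 3 of 10, 9 of 20 and 4 of 5 of these families rose, in the same order. Of 60 histone genes 54 fell and 0 rose (-2.53), and of 31 kinesins 18 fell and 6 rose (-0.9). With library size alone the median of all genes moved by 0.08, less than any of these medians.

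The direction of change went with the span of a gene on the genome. Among protein-coding genes with a mean log2 CPM of at least 0, 17.5% rose and 38.7% fell on average in the fifth with the shortest spans (median 5.83 kb, taken from the GENCODE annotation of GRCh38). In the fifth with the longest spans (median 155 kb) 40.2% rose and 21.8% fell. Across genes, which are not independent replicates, Spearman's rho of span and log2 fold change was 0.21 with shRNA 1 and 0.2 with shRNA 2. Spans were known for 96.0% of the 11713 protein-coding genes at that level, and no explanation was tested.

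The protocadherin beta genes rose in 16 of 18 with shRNA 1 and 18 of 18 with shRNA 2, with median log2 fold changes of 4.29 and 6.97, or 4.22 and 6.95 with genes at 0 in the controls at their bound. PCDHB7 had 0 counts in the controls and was at least 31-fold higher with shRNA 1 and at least 239-fold with shRNA 2, against 3 counts over the controls. Genomic DNA in the shRNA libraries was argued against as the whole cause. The other 104 intronless genes under 1 CPM in control had a median of 0.34 on average, under the bound of 0.5. Of these, 25 were called higher and 14 lower. The 95% interval of the median, 0.09 to 0.66, reached above 0.5 but stayed under 1. The interval and its limit of 1 were added after the median was seen. Reads shared between the members cannot be told apart from a rise of each, because only 2 members share under 10% of their words (both, 2, were higher). Of 15 measured members other than PCDHB19P, the most abundant, 3 lay above a bound on reads lent by it. That bound took every word that a member shares with any gene as shared with PCDHB19P. Only 5.1% of the words of PCDHB19P itself occur in another gene, so the bound can lie too high and decides nothing. A shared change of the cluster stays a hypothesis; in the related clusters, whose members share exons and so counts, 22 of 23 protocadherin gamma genes (median 0.54) and 3 of 8 protocadherin alpha genes (median 0.78) rose on average, against a median of 5.68 for the beta genes, but with shRNA 1 alone 7 of 23 gamma (median 0.37) and 3 of 8 alpha genes (0.82) rose, and with shRNA 2 alone 22 of 23 (0.7) and 1 of 8 (0.73).

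Of genes near the protocadherin clusters, SLC25A2 rose by 4.07 and TAF7 fell by 0.52 on average. HDAC3 (-0.05), DIAPH1 (-0.03) and ZMAT2 (-0.23) did not pass on average, and ZMAT2 fell by 0.49 with shRNA 2 (edgeR adjusted p = 0.00591).

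Of the 502 genes lost in shRNA 2 replicate 1, 262 lay at under 0.05 of the other libraries, and lower depth was argued against as the whole cause, since 284 had an expected count of at least 1000; a first bound of 100 was met by all 502 by construction and was replaced after that was seen. Reads with several places may have been left out of this library: of genes with at least 50% of their words shared 39.7% were lost, against 1.7% of those with none, and 17 of 17 pseudoautosomal genes, which have a copy on both sex chromosomes, were lost. Between these groups, 1.4% of genes with under 10% of their words shared and 10.0% of those with 10% to under 50% were lost. The share of 39.7% lay between the bounds. It cannot count against this explanation, because a gene with only part of its words shared can keep reads from the rest. Loss was thus most frequent where most words were shared, but 84 genes with no shared word were also lost. Whether all such reads were left out stays open. All genes compared from HLA-F to HLA-DPB1, for which alternative haplotype sequences exist, were lost (103 of 103, 100%, against 6.9% on the rest of chromosome 6), which is consistent with the loss of reads that have a copy on such sequences. Of the lost genes 76.7% lay in the HLA interval, were pseudoautosomal or had at least 10% shared words, but only 429 of the 502 had a measure of shared words and other haplotype copies were not searched for, so the source of the rest stays open, and no biological explanation was tested.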
